A study of Arabidopsis thaliana with 4 samples.

How the data were processed

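RNA from Arabidopsis thaliana pollen and stamens was hybridised to Affymetrix ATH1 arrays, which carry short oligonucleotide probes grouped into probe sets. The 4 arrays cover wild type pollen, wild type stamens, CaMV::DME pollen and CaMV::DME stamens, with 1 array per group. Flowers were at stages 13 and 14, per the labels. The titles of the wild type samples name both Columbia glabrous and C24 as the plant background. Which of them applies was not settled here. The titles of the CaMV::DME samples name neither. Any difference in background would coincide with the transgene in both tissues, and was not tested. Per the labels' protocols, RNA was selected for poly(A) tails before labelling.

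The deposited values are intensity values on a linear scale, 1 per probe set and array. Per the submitters' processing notes, GCOS 1.3 was used. The probe set summary and the scaling settings are not given in the sources used here. The mean of the deposited values without the outer 2% at each end lay between 500.0 and 500.1 on all 4 arrays, a property of the values that global scaling by the authors would give. No detection calls were used, so a dim probe set has no measured background limit of its own.

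Of 22810 probe sets, 64 control probe sets were left out of all comparisons, leaving 22746. Each array was multiplied so that its trimmed mean over these probe sets equalled their mean over the 4 arrays, 495.4, here called T. The factors lay between 0.997 and 1.002. Signals under 0.1 T (49.5) were then set to that floor and log2 was taken. Values at the floor have no order, so a ratio with a floored side is a lower bound and is written as "at least" or, for a negative log2 ratio, "or lower". Medians of lists take such ratios at the bound. A probe set counted as measured in a comparison where its brighter array reached 0.4 T (198.2), and as higher or lower where it also differed by 2-fold or more. The words rose and fell are used of such calls. They are calls of size, with no test, because 1 array per group leaves no replicate error.

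A single test used all 4 arrays. limma 3.58.1 (lmFit and eBayes with a trend, in R 4.3.3) was fitted with tissue as a block over the 11827 probe sets that reached 0.4 T on at least 1 array, with Benjamini-Hochberg adjustment at 0.05. Its only residual degree of freedom is the difference between the effects in the 2 tissues. Beside that 1 degree, limma drew 13.8 prior degrees of freedom from the other probe sets, with a trend on signal. Its p-values thus weigh the mean effect mainly against that shared spread. A probe set can pass although its ratios in the 2 tissues differ in size. The p-values do not tell whether the change would be seen again in new plants.

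Probe sets were named from GEO's platform annotation, with symbols updated through gene identifiers from the TAIR10.1 RefSeq table. Among the 22746 probe sets, 13513 had 1 gene symbol, 503 had several and 8730 were unnamed here. Of those with 1 symbol, 13436 were matched to a RefSeq gene. Of 301 genes on the 16 lists fixed before the data were examined, 44 had a named probe set, and 2 lists had none. MEA, FWA and FIS2 are among the genes with no named probe set here and were not analysed. No coordinates are given because no genome build is named for the array.

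A list's shift is given as the median log2 ratio of its probe sets and, for lists of 3 or more probe sets, the percentile of that median among 10000 random lists matched on mean log2 signal in 20 bins. Percentiles describe these arrays only. Further families were chosen from the annotation after the files were read but before any ratio was computed. The mitochondrial genes, the nuclear photosynthesis genes found by symbol and the tapetum lipid transfer proteins were chosen after ratios were seen. 95% intervals of list medians come from 2000 bootstrap resamples of probe sets, which are not independent replicates.

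The rule for named genes was fixed before the data were examined. It takes DME and the imprinted genes MEA, FWA, FIS2 and MPC on every array, of which MPC alone has a named probe set here. It takes, per tissue, the 10 largest rises and falls measured on both sides and up to 5 each with 1 side at the floor, taken by the brighter array, among probe sets of exactly 1 gene. It also takes up to 4 called members per list and tissue, the 8 largest rises and falls shared by both tissues among probe sets of exactly 1 gene, and up to 3 called members per marker list for wild type pollen against stamens. Probe sets whose identifier ends in _x_at, which can bind transcripts of other genes, were not taken as largest, floored or shared changes. Members of a family or list named with their values, and probe sets with no name here, fall outside this rule. Unnamed probe sets are described by their signals.

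Both calling steps were tested on simulated data. In 10 simulations of the limma step on the 11827 probe sets tested with 200 changed, 29 to 43 of 50 probe sets changed 4-fold and 46 to 50 of 50 changed 8-fold were called, against 2 to 13 of 50 changed 2-fold. Between 2.9% and 12.7% of the calls were false (8.01% over all simulations), so the adjusted p-values were somewhat too small in that setting. The simulated noise was normal and depended on mean signal only, as limma's trend assumes. The share of false calls in the real data may therefore be higher and is not known. For the rule of size, pollen and stamen pairs were simulated with noise of the same size for all probe sets, dim or bright. Its size was the robust standard deviation of the real log2 ratios, 0.42 in pollen and 0.72 in stamens, taken wholly as noise. In pollen, 18 of 50 probe sets changed 2-fold and 50 of 50 changed 4-fold were called, beside 154 unchanged among 6926 measured. In stamens, 28 and 48 of 50 were called, beside 1932 unchanged among 10479 measured. Because this noise did not vary with signal, false calls are understated wherever the real spread is wider, as it may be among dim probe sets. The simulated counts therefore do not give the share of false calls among the real calls of size.

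Alternatives covered the scaling, the floor, the brightness filter, the size of fold, a rule based on robust standard deviations, the removal of probe sets that may cross-hybridise, and limma's settings. Scaling by the hybridisation spikes was added after seeing the data. A gene's ratio or a list's median counts as moved where it shifted by more than the robust standard deviation of that comparison's log2 ratios, 0.42 in pollen and 0.72 in stamens. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The number of arrays limits the precision of every value.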

Results

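Transcript levels were measured on 4 ATH1 arrays from pollen and stamens of wild type Arabidopsis and of plants carrying CaMV::DME, in which a cauliflower mosaic virus promoter drives DEMETER (DME). DME is a DNA glycosylase that removes 5-methylcytosine. The series set out to find putative DME target genes by inducing the gene in tissues where, per its design text, it is not active in wild type. Each group holds 1 array, so no value below has a replicate error, and all calls within a tissue are calls of size. The number of probe sets reaching the brightness limit was 6339 in wild type pollen, 6753 in CaMV::DME pollen, 8969 in wild type stamens and 10252 in CaMV::DME stamens. Between 29.5% and 36.0% of probe sets lay at or below the floor.

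DME itself was dim on all arrays. Of its 3 probe sets, 1 was called, with a signal of 78.7 in wild type and 220.9 in CaMV::DME stamens, a log2 ratio of 1.49. The other 2 went from below the floor in wild type stamens to 92.9 and 98.9, under the brightness limit. In pollen no DME probe set reached that limit. Their pollen signals were 127.5 in wild type and 70.0 in CaMV::DME for the first of them, 21.4 and 118.8 for the next, and 65.1 and 55.6 for the one called in stamens. DME therefore does not check the label of the CaMV::DME pollen array. MPC, an imprinted gene, gave 60.2 and 120.9 in wild type and CaMV::DME pollen and 138.6 and 29.2 in the stamen arrays, too dim to be called.

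**Figure D1:**
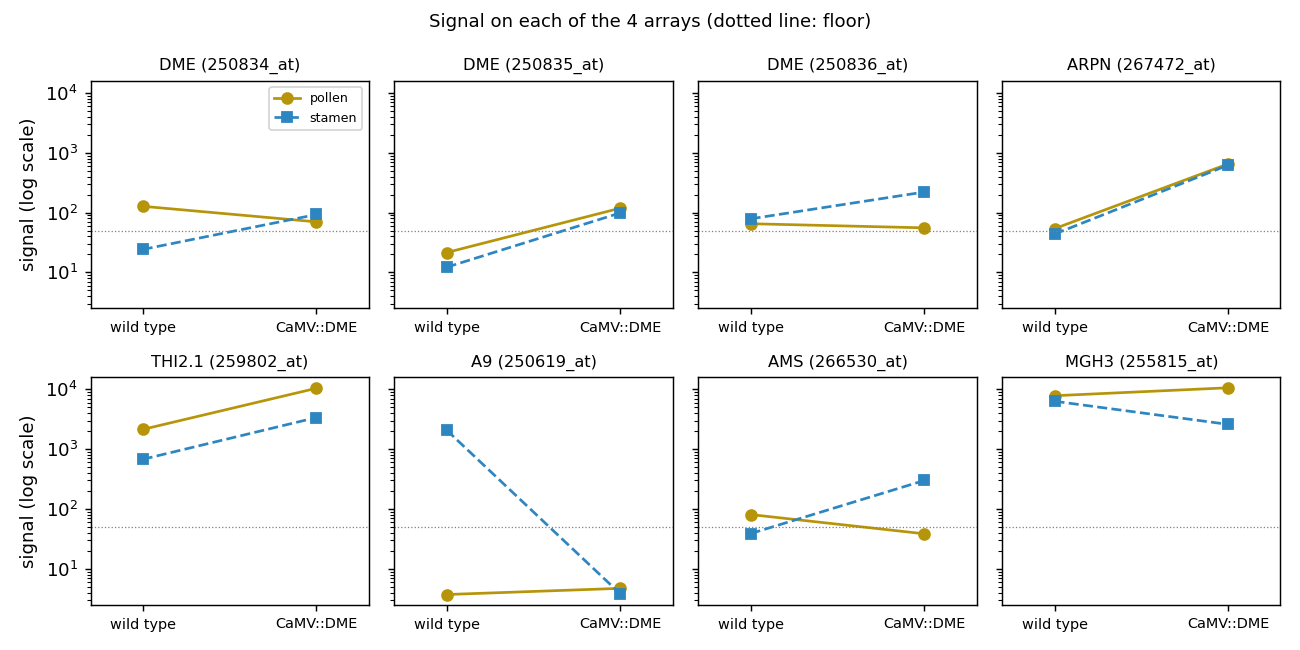
Signal, on a log scale, of 8 probe sets on each of the 4 arrays, with wild type at the left and CaMV::DME at the right of each panel; circles are pollen, squares are stamens, and the dotted line is the floor. ARPN and THI2.1 are higher on both CaMV::DME arrays, A9 went from 2086 to 3.79 in stamens, and the DME probe sets reach at most 220.9 on any array.

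The first comparison asked which transcripts differ between the array labelled CaMV::DME pollen and wild type pollen. ARPN, a plantacyanin (a small blue copper protein), showed the largest named rise measured on both sides, from 53.8 to 654.0 or 12.2-fold. THI2.1, an antimicrobial thionin, rose 4.89-fold from 2142 to 10470. The other large rises were AT1G71840 (8.15-fold), AT1G18210 (5.83-fold), AT4G26940 (4.92-fold), the glucosyltransferase gene UGT76E2 (4.55-fold), the geranylgeranyl reductase gene AT1G74470 (4.53-fold), AT1G42960 (4.51-fold), AT1G30880 (4.50-fold) and AT3G15450 (4.39-fold). From below the floor, the plastid ribosomal protein gene rps4 rose at least 8.95-fold, PSAE-1 of photosystem I at least 7.06-fold, AT1G52670 at least 7.04-fold, AT3G22440 at least 6.15-fold and AT5G22450 at least 6.03-fold. The largest fall among named genes was AT1G36105, a pseudogene in RefSeq, 19.0-fold from 1178 to 62.0. It was followed by AT1G73170 (log2 ratio -3.33), AT1G31910 (8.18-fold), AT1G34660 (7.97-fold) and AT1G20910 (4.71-fold). The serine carboxypeptidase-like gene scpl33 (3.90-fold), the ubiquitin-conjugating enzyme gene UBC29 (3.86-fold), AT1G34470, AT1G75150 and AT3G15520 also fell. To below the floor fell AT4G22610 (at least 6.16-fold), AT5G06930, AT5G59190, AT1G76240 and AT1G79890.

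In all, 503 of 7322 measured probe sets were higher (6.87%) and 199 lower (2.72%) in CaMV::DME pollen. The share of calls that were rises, 71.7%, was 51.9% with quantile normalization, 59.1% with loess and 88.0% with spike scaling. Of the rises, 288 (57.3%) belonged to probe sets at least 2-fold brighter in wild type stamens than the mean log2 signal of both pollen arrays, against 37 of the 199 falls (18.6%) and 20.5% of all measured probe sets, a comparison chosen after the data were seen. None of 11 measured vegetative cell and pollen tube probe sets was called (median log2 ratio 0.00, between -0.07 and 0.09 over the scalings), and the sperm genes MGH3 and TET11 gave 0.44 and -0.02. None of the 2 measured DNA methylation probe sets and none of the 3 measured heat shock probe sets was called, the latter with a median of -0.37. Among 9 measured MADS-box probe sets, AGL21 fell 2.08-fold and no other was called. No other fixed list had a called member in pollen, but many could show little. The 3 probe sets of the tapetum list were not measured there. Nor was any probe set of the floral organ, seed, salicylate and defence, touch or transposable element lists. The Polycomb, jasmonate and ribosomal protein lists had no named probe set. The imprinted, photosynthesis, F-box, and cold and drought lists had 1 measured each.

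The second comparison asked the same in stamens. CYP71B31, a cytochrome P450 gene, rose 38.0-fold from 88.2 to 3350, the largest rise. AT3G43960 (33.5-fold), AT5G40450 (29.7-fold), AT4G00040 (19.1-fold), the cell wall enzyme gene XTH19 (log2 ratio 4.19), the ATP sulfurylase gene APS4 (16.5-fold), AT5G38130, the auxin glucosyltransferase gene IAGLU (13.3-fold), AT1G64370 and AT5G48460 (12.6-fold) followed. From below the floor rose the trihelix factor gene GT2 (at least 15.8-fold), AT2G37130 (at least 15.8-fold), AT1G23650, ARPN (at least 12.6-fold) and AT5G43450 (at least 12.5-fold). The named falls were led, among those measured on both sides, by the endoglucanase gene GH9C3 (26.2-fold), the plastid gene psaI (25.9-fold), AT1G02813 (25.4-fold), AT5G17340, and the plastid ATP synthase gene atpA (19.6-fold). AT5G03590, AT2G04020, atpH (12.9-fold), AT5G15360 (12.3-fold) and the glucosinolate gene AOP3 (10.6-fold) also fell. To below the floor fell AT5G62080 (at least 47.9-fold), the tapetum gene A9 (at least 42.1-fold), AT3G07450 (at least 23.4-fold), AT3G52130 (at least 20.4-fold) and the plastid gene accD (at least 13.7-fold). An unnamed probe set, picked out after its values were seen, went from 10530 to below the floor, at least 212.6-fold.

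Among the marker lists in stamens, the sperm histone gene MGH3 fell 2.44-fold, the second measured sperm gene TET11 gave a log2 ratio of -0.29, and 2 of 11 pollen list members fell, the actin gene ACT11 (2.04-fold) and AGL29 (2.94-fold). Their list's median was -0.38, the 15.5th percentile of random lists, and lay between -0.38 and 0.08 over the scalings. Of 3 tapetum list members, A9 fell, the regulator AMS rose at least 6.06-fold from below the floor to 300.1, and EXL5 went uncalled from 1253 to 863.9. Both measured photosynthesis list members rose, RCA by a log2 ratio of 1.23 and LHCB4.2 by 2.81. SPL, a regulator of early anther development, rose 2.16-fold, and the stress genes LTI30 (a dehydrin) and STZ (a zinc finger factor) fell 2.72-fold and 2.57-fold. None of the 4 reference probe sets was called, with a median of -0.13 that became 0.33 with spike scaling. AGL29 was the only one of 8 measured MADS-box probe sets called, and the called DME probe set the only one of 2 measured in the DNA methylation list. No other fixed list had a called member in stamens. Of these, the seed, salicylate and defence, and transposable element lists had no measured probe set. The imprinted, carpel, heat shock, pectin enzyme and F-box lists had 1 measured each. Control ratios also differed between the stamen arrays, with an actin 5' to 3' ratio of 0.481 in wild type and 0.297 in CaMV::DME, a GAPDH ratio of 0.809 and 0.704, and a 25S ribosomal RNA signal 3.81-fold higher in CaMV::DME.

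Plastid-encoded probe sets, a family chosen from the annotation, had a median log2 ratio of -1.17 in stamens (95% interval -1.56 to -0.89), below all 10000 random lists and between -1.46 and -0.92 over the scalings. Of 37 measured, 31 fell and 2 (rpl16 and rps3) rose. In pollen 1 of 12 measured, rps4, rose and none fell.

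**Figure D2:**
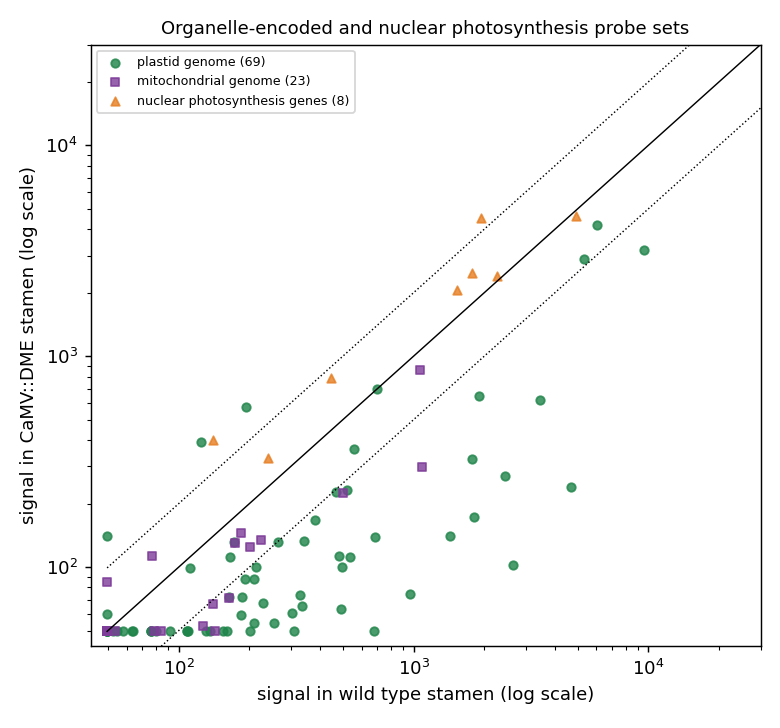
Signal in CaMV::DME stamens (vertical) against wild type stamens (horizontal), both on log scales and floored, for 69 plastid-encoded, 23 mitochondrial and 8 nuclear photosynthesis probe sets; the solid line marks equal signal and the dotted lines a 2-fold difference. Of the 69 plastid-encoded points, 58 lie under the line of equal signal, and the nuclear photosynthesis points lie near or above it.

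Over all stamen probe sets, 1702 of 10778 measured were higher (15.8%) and 460 lower (4.27%). Rises made up 78.7% of the calls, against 58.7% with quantile normalization, 62.5% with loess and 95.2% with spike scaling. The median log2 ratio of the measured probe sets was 0.12, and spike scaling moved it to 0.58. Without replicates, these counts cannot be divided into change and spread between arrays.

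The fit of a CaMV::DME effect shared by both tissues called 4 probe sets higher and 1 lower of 11827 tested with limma (755 at an unadjusted p under 0.05). THI2.1 had a log2 effect of 2.31 ± 0.29 (SE; limma adjusted p = 0.0039) and ARPN of 3.63 ± 0.50 (limma adjusted p = 0.0075). A pair of unnamed probe sets were also higher, with log2 effects of 2.28 and 3.09. An unnamed probe set was lower by 69.9-fold in pollen, from 48770 to 697.9, and by 6.80-fold in stamens, from 12520 to 1843, a call that limma's robust option ended (limma adjusted p = 0.837, between 2.4e-06 and 0.843 over the alternatives). Each moved the same way on both pairs of arrays. No probe set passed in limma without its trend (624 at an unadjusted p under 0.05) or with no brightness filter (641), and ARPN had 1 side at the floor in stamens, as the probe set with an effect of 3.09 had in pollen.

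Among 6273 probe sets measured in both tissues, 60 were higher in both, where independent lists would share 34.0, and 7 were lower in both, against 3.34. Another 17 rose in pollen and fell in stamens (14.2 for independent lists) and 17 did the opposite (7.99). The numbers for independent lists take every probe set as equally likely to be called. Calls in opposite ways exceeded them too (34 against 22.2), so the excess alone does not show a shared effect. After ARPN and THI2.1, the shared named rises were led by AT5G22450, ATMAP65-6 (a microtubule-associated protein gene), AT5G48570, AT3G51950, AT5G59540 and AT5G65750. The shared falls with a single gene were AT5G15360, AT3G47310, AT1G43590 and AT1G31910. Across the 4811 probe sets bright on all arrays, the log2 ratios in the 2 tissues had a Pearson correlation of 0.090 and a Spearman correlation of 0.108. This is a correlation across probe sets, which are not independent replicates.

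**Figure D3:**
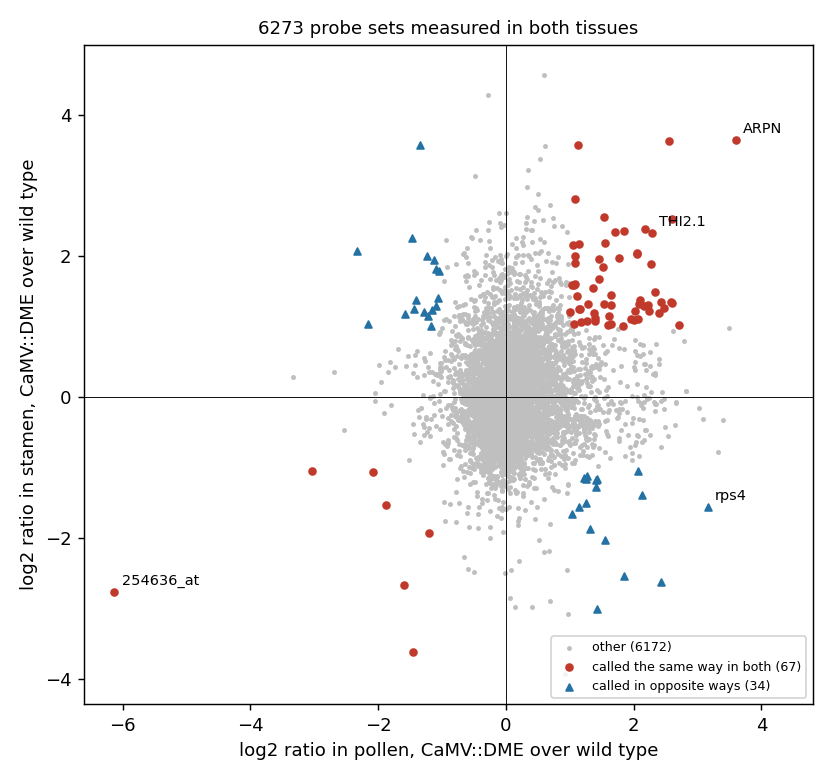
Log2 ratio of CaMV::DME over wild type in stamens (vertical) against pollen (horizontal) for 6273 probe sets measured in both tissues; circles are called the same way in both (67), triangles in opposite ways (34), and grey points are the rest. ARPN and THI2.1 lie at the upper right, and the unnamed probe set that limma called lower, labelled by its identifier, lies at the lower left.

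Wild type pollen was set against wild type stamens, which contain pollen, to check the labels. The pollen list was higher in pollen in 10 of 11 measured probe sets, led by the receptor kinase gene ANX1 (4.99-fold) and the MADS-box genes AGL65 (4.76-fold) and AGL30 (4.57-fold). A9 (at least 42.1-fold), EXL5 (at least 25.3-fold), RCA (13.5-fold) and LHCB4.2 (2.94-fold) were lower in pollen. INO, an ovule gene, was 2.89-fold higher in pollen, at a signal of 208.3 near the brightness limit. Of 10138 measured probe sets, 2776 were higher and 4507 lower in pollen. The share higher, 38.1% of calls, was 55.2% with quantile normalization and 1.66% with spike scaling, while the median log2 ratio of -0.58 became 0.03 and -1.995, so the balance between the tissues depends on the scaling.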

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

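Chosen after the results were seen were the test of pollen rises against 0.5 of the stamen signal, the repeat with a set chosen without the CaMV::DME pollen array, the median over probe sets kept by their mean pollen signal (the third criterion tried for stamen RNA, after medians over all members, which fell under some scalings, and over measured members, a filter that depends on the change), the tests of a lower pollen share as the whole cause and of younger anthers, the 3 tests on plastid-encoded probe sets, and spike scaling.

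Effects ran in opposite directions in the 2 tissues for 17 probe sets higher in pollen and lower in stamens, and for 17 lower in pollen and higher in stamens. The difference between the tissues was not tested, since each group holds 1 array. Named cases were rps4 (log2 ratio at least 3.16 in pollen and -1.55 in stamens), AT5G06930 (-2.33 or lower and 2.07), AT1G76240 (-2.16 or lower and 1.03) and the mitochondrial gene cox1 (1.32 and -1.87), the last from a family chosen after ratios were seen.

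Control probe sets, which no comparison used, also differed. The 25S ribosomal RNA control was higher in CaMV::DME stamens by a log2 ratio of 1.93. In pollen, 3 actin controls were higher, by 1.32 (middle), 1.15 (3' end) and 1.35 (5' end). The 3' control read 264.3 in wild type and 585.1 in CaMV::DME pollen. It was far brighter in stamens, at 8627 in wild type and 6026 in CaMV::DME.

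The first pattern is the 503 rises in CaMV::DME pollen. RNA from other stamen cells, taken without spread between arrays, is argued against as the whole cause. Of the rises, 41.2% gained more than 0.5 of their stamen signal. Any rise whose mean stamen signal was under the brightness limit passes that bound by the rule of calling alone. Stamen RNA together with spread between arrays is not excluded, since rises were selected for their gain. Relative to stamen signal, 79.5% of the rises gained more than nearly all of 351 probe sets much brighter in stamens. The bound here, a gain of 0.115 of stamen signal, is lower than 0.5. Rises with a stamen signal well above the brightness limit therefore also pass it by the rule of calling alone, so this share adds little. These 351 were chosen without the CaMV::DME pollen array, not for their gain. With 297 such probe sets chosen on all arrays the share was 93.2%, which decides nothing because that choice limits their gain. Some stamen RNA is consistent with the median of these 297, 0.23 (95% interval 0.05 to 0.45, but 0.04 to 0.23 over the scalings and 0.00 with a floor of 0.2 T), and with that of the 153 whose mean log2 signal over both pollen arrays reached 0.2 T, 0.55 (109 ratios above 0 and 44 below, and a median of 0.43 to 0.69 over the scalings). Spread between arrays and an effect of DME, also on these genes, stay open. They were not tested, as no second pollen sample of either genotype was analysed here. Any difference in plant background stays open too.

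The second pattern is the difference between the stamen arrays, and a different share of pollen is consistent with it: the median ratio of probe sets brighter in stamens (0.12) exceeded that of probe sets brighter in pollen (-0.37, or 0.09 with spike scaling) by 0.48. Taken without spread between arrays, a lower share of pollen cannot be the whole cause of the rises. The probe sets brighter in stamens would all have to rise together by 1 or more, but had a median of 0.12 (0.57 at most over the scalings). A lower share together with spread between arrays is not excluded, since rises were selected for their size. Younger anthers with tapetum in the wild type sample cannot be told apart from an effect of the transgene. The 5 tapetum lipid transfer protein loci had a median of -4.55 or lower, all being at the floor in CaMV::DME, but the set was chosen because its members fell. On the tapetum list fixed before the data were examined, A9 fell, AMS rose and EXL5 was not called. The genotype, any difference in plant background, and RNA quality stay open, untested, the last since the actin 5' to 3' ratio differed too (0.481 and 0.297).

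The third pattern is the fall of plastid-encoded probe sets in CaMV::DME stamens. Less green tissue is argued against by the nuclear photosynthesis probe sets, whose median was 0.47 (95% interval 0.08 to 1.23). That list was chosen after ratios were seen, and it leaves out LHCB4.2, which rose in stamens, and PSAE-1. The scaling is argued against too, since the plastid median stayed at -0.92 or lower under all 6 scalings, the reported one included. Less carry-over of RNA without a poly(A) tail cannot be told apart. The 25S control went the other way (1.93), but it is 1 probe set. The mitochondrial probe sets had a median of -0.34 (0.0th percentile of random lists), which was -0.64 with quantile normalization, -0.70 with loess and 0.00 with spike scaling. An effect of the transgene on plastids was not tested.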

How the results depend on the processing

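No paired analysis was possible because each group holds 1 array, so no numbered replicates pair samples; the limma fit with tissue as a block sets genotypes against each other within tissues. Spike scaling was chosen after seeing the data; all other settings were fixed before. Of 156 counts under alternatives, 87 stayed within 1.5 times the reported count. The cause of the other shifts was not tested, apart from filters and folds, which change the probe sets that can be called. No call within pollen or stamens changed direction under any setting. Turning a call would need a ratio of 2-fold or more to become one of 2-fold or more the other way. Settings of fold, brightness and probe removal, and the robust rule, leave ratios unchanged and could not do so. The floors of 0.05 T and 0.2 T cannot change a call at 2-fold and 0.4 T, and a filter at 0.2 T equals no filter, so these settings are no evidence of stability.

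In the order higher and lower in pollen, 503 and 199 became 870 and 806 with quantile normalization, 1657 and 1055 with a filter at 0.2 T or none, 154 and 41 at 0.8 T, 183 and 56 at 3-fold, 112 and 49 by the robust rule, and 198 and 27 with spike scaling. The lower count was 105 with a pseudocount. In stamens, 1702 and 460 became 1034 and 727 with quantile normalization, 759 and 162 at 3-fold, 318 and 125 by the robust rule, and 4226 and 211 with spike scaling, and the higher count was 984 at 0.8 T. For wild type pollen against stamens, 2776 and 4507 became 598 and 806 by the robust rule and 121 and 7153 with spike scaling. The higher count was 4196 with quantile normalization and 1503 at 3-fold.

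Probe sets higher in both tissues, lower in both, higher in pollen with a fall in stamens, and the opposite numbered 60, 7, 17 and 17. They became 227, 38, 67 and 103 with a filter at 0.2 T or none, 13, 3, 8 and 3 at 0.8 T, 11, 2, 2 and 1 at 3-fold, 7, 1, 6 and 1 by the robust rule, and 36, 4, 3 and 2 with spike scaling. Quantile normalization gave 22, 42 and 37 for the last 3, loess 34 and 14 for the first 2, and the pseudocount 38 for the first and 7 for the last.

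The shared limma effect, 4 higher and 1 lower, gave 0 and 0 without the trend (624 at an unadjusted p under 0.05) and with no filter (641), and 8 and 3 with a floor of 0.2 T. The lower count was 0 with the robust option and 3 with 0.4 T on all 4 arrays. Of 3746 gene ratios under alternatives, 3505 moved by less than the spread and 0 called ones changed sign. A change of sign would take the loss of a whole 2-fold difference, so its absence is weak evidence of stability. Of 924 list medians, 919 moved by less than the spread. Many of these medians were 0 under most scalings because their members lay at the floor, and most were smaller than the spread allowed. The count of medians is therefore little evidence of stability. Dim probe sets limit the rest: 29.5% to 36.0% of each array lay at the floor.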

Other observations

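Several families chosen from the annotation were called in 1 direction only in stamens, without a test. Of 9 measured ubiquitin-specific protease probe sets 2 rose and none fell, with a median of 0.31 over these 9 and of 0.94 over all 12, dim ones included (99.2nd percentile of random lists, 0.47 to 1.39 over the scalings); 15.8% of all measured probe sets rose. Of 6 measured IQ-domain probe sets 4 rose, iqd32, IQD28, IQD19 and IQD31, with a median of 0.50 over all 15 (97.4th percentile, 0.23 to 1.08). Of 13 measured UDP-glucosyltransferase probe sets 6 rose and none fell, and of 4 measured cytochrome P450 probe sets 3 rose, CYP71B31, CYP71B38 and CYP78A9. Counts among measured members can be raised by the rises themselves, since a probe set is measured where its brighter array reaches the limit. All the ubiquitin-specific protease, IQ-domain and cytochrome P450 probe sets that rose, and 3 of the 6 UDP-glucosyltransferase ones, reached it on the CaMV::DME array alone. Over all 47 UDP-glucosyltransferase and 26 cytochrome P450 members, most of them not measured, both medians were 0.00 (up to 0.40 and 0.73 over the scalings). The SWEET sugar transporters split, with SWEET9 and SWEET11 higher and SWEET10 and SWEET2 among 3 that fell.

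In pollen, the family medians highest among random lists were those of cation/proton exchangers and nuclear photosynthesis genes. The exchangers had 0.33 (99.4th percentile, 0.02 to 0.33 over the scalings, none of 3 measured called). The photosynthesis genes, chosen after ratios were seen, had 0.56 (99.3rd percentile, 2 of 5 measured higher). Their list leaves out PSAE-1 and LHCB4.2. The lowest family percentile in pollen was that of the serine carboxypeptidase-like genes (-0.09, 1.4th percentile). In stamens, the tetraspanins (-0.17, 1.3rd percentile) and the same exchangers (-0.29, 3.6th percentile) were low. So were the mitochondrial probe sets, chosen after ratios were seen (0.0th percentile, 2 of 5 measured lower and none higher). In pollen their median was 0.205 (95.4th percentile, 0.00 to 0.207 over the scalings, 3 of 6 measured higher and none lower). Among 59 measured pseudogene loci, 5 rose and 11 fell in pollen. In stamens, 3 of 16 rose and 4 fell.

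Percentiles were computed for 33 lists in each tissue, so some this far out would be met by chance.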
